A study of Homo sapiens with 24 samples.

How the data were processed

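Gene expression was measured on 24 single-colour Affymetrix expression arrays hybridised with RNA of human primary natural killer (NK) cells. The cells had been cultured with an agonist antibody to CD158d, the protein encoded by KIR2DL4, or with a control immunoglobulin, for 4, 16 or 64 h. Each of the 6 groups of treatment and time held 4 arrays. The labels numbered the replicates of every group from 1 to 4 and named 4 donors, without saying what a replicate number stands for. Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples.

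The deposited values were linear signal intensity per probe set, made by the authors with GCOS 1.4 per the processing notes of the labels, which do not state the algorithm or the scaling target. The mean of the signals between percentiles 2 and 98 was between 1249.9 and 1250.1 on all 24 arrays, while the median signal ranged from 321.76 to 445.24, so the arrays had been scaled by a trimmed mean and had not been quantile normalized. All signals were above 0, from 0.181 to 652930. The arrays' number limits the precision of every value.

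The table held 54675 probe sets. Of these, 62 were hybridisation or spike controls, 41091 were assigned to 1 gene, 1801 to several genes and 11721 to none. Gene symbols were taken from the platform's probe table and matched by Entrez ID to RefSeq genes for 41037 probe sets. The 95 probe sets of Y-linked genes and XIST were left out throughout. Each gene was represented by the probe set with the highest mean log2 value over the 24 arrays, which gave 19740 genes. Signals were transformed as log2(signal + 16). Genes with a mean log2 value under the 40th percentile, which lay at a signal of 230.02, were not tested, which removed 7896 genes and left 11844.

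Differences were tested with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), by a linear model of the 6 groups over all 24 arrays and empirical Bayes moderation with a trend on mean log2 value. The fit left 18 residual degrees of freedom. Agonist was compared with control at each of the 3 times, the agonist effects were compared between times as interactions, and control at 16 h and at 64 h was compared with control at 4 h. The p-values of each of these 8 comparisons were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and all tests were two-sided. Error values of log2 fold changes are the standard errors of the fit. The level of KIR2DL4 was also tested by an exact two-sided permutation test at each time, and by an exact sign-flip test of the differences between arrays of the same replicate number.

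Genes were named by rule. For each agonist comparison the rule named the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose 4 agonist arrays all lay above, or all below, the 4 control arrays, and the 5 genes with the smallest p where none passed. For interactions and control comparisons the numbers were 5 and 5. Up to 4 members per gene list, those with the smallest p, were named as well, and KIR2DL4, CDKN1A, TP53, IL6, CXCL8, TNF, IFNG, NFKBIA and PRKDC were always included. TP53 had no probe set assigned to it alone and has no value. HLA genes, other KIR genes and immunoglobulin genes, whose probes depend on alleles or near-identical copies, were counted and not named. Further genes were named after their values were seen: the aminoacyl-tRNA synthetases and MTHFD2 at 16 h.

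Gene lists numbering 30, with 557 distinct members, were written from general knowledge of NK cells and of the study's subject. They covered NF-kB targets, cytokines and chemokines, the senescence-associated secretory phenotype, p53 targets, cell cycle inhibitors and senescence markers, the DNA damage response, proliferation, cytotoxic machinery, NK cell receptors and adaptors, activation markers and cytokine receptors, interferon-stimulated genes, angiogenesis and vascular remodelling factors, immediate early genes, apoptosis inhibitors, apoptosis promoters, glycolysis and hypoxia, cholesterol synthesis, the unfolded protein response, heat shock, ribosome biogenesis, metallothioneins, NK transcription factors, antigen processing, and markers of monocytes, B cells, T cells, dendritic cells, platelets, erythroid cells and neutrophils. Several genes belong to more than 1 list. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, and p-values were adjusted over the 30 lists of a comparison. The same test with the correlation estimated from the data, and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. The comparisons, tests, lists and naming rule were set before the data were examined.

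Whether replicate numbers pair the samples was checked on deviations from the group means. The 60 pairs of arrays with the same number in different groups correlated at 0.192 to 0.491, and the 180 pairs with different numbers at -0.286 to 0.0920. For 24 of 24 arrays the best-correlated array carried the same number, so the numbers pair samples across groups. The fit without a replicate term had been chosen as the first analysis, and the fit with the replicate number as a block is given where it changes a call or a count. The fitting code was tested on simulated data with 200 changed genes among 11844. With replicate effects in the simulated arrays, the fit without a block recovered 26 % of changes of log2 size 1 and 78 % of those of size 2, and the fit with a block recovered 54 % and 90 %. The unchanged genes called numbered 1 without the block and 7 with it.

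The alternatives tried were offsets of 1 and 64, quantile normalization, a shift of each array to a common median, no filter, a filter at the 60th percentile, every probe set tested on its own, the replicate number as a fixed or a random block, only the arrays of the comparison, no trend, array weights, robust moderation, and leaving out each array in turn. An offset of 256, leaving out all 6 arrays of replicate number 1, leaving out each replicate number from the similarity of the agonist effects, repeating the list tests without each array, and the sign-flip test of KIR2DL4 were chosen after seeing the data. Fits that left out arrays had no replicate block. RNA quality was read from the ratio of 3' to 5' control probe sets of ACTB and GAPDH. Probe sets without a gene of their own were tested only in the alternative that tests every probe set.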

Results

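Natural killer (NK) cells are lymphocytes of innate immunity that kill target cells and secrete cytokines. KIR2DL4 (CD158d) is an NK cell receptor that resides largely in endosomes and binds soluble HLA-G, a molecule made by fetal trophoblast cells. The study asked how triggering this receptor with an agonist antibody changes gene expression over time, with senescence and vascular remodelling as its subject. Expression was measured on 24 arrays, 4 for each of the agonist and control cultures at 4, 16 and 64 h. Median signal intensities ranged from 322 to 445 between arrays, and the number of arrays limits the precision of each value.

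The level of the receptor's own transcript was compared first. KIR2DL4 was abundant in all 6 groups. Its mean log2 value was 11.59 ± 1.26 in control and 11.99 ± 1.00 in agonist cultures at 4 h, 11.84 ± 1.04 and 11.84 ± 0.40 at 16 h, and 12.09 ± 0.70 and 13.06 ± 0.44 at 64 h (SD, n = 4 each). The log2 difference was 0.39, 0.0010 and 0.97 at the 3 times, with a standard error of 0.54. The exact two-sided permutation p was 0.6, 1 and 0.0571, where 70 permutations allow a smallest value of 0.0286. Adjusted by Benjamini-Hochberg over the 3 tests, the exact p was 0.9, 1 and 0.171, so no difference passed. With 4 arrays per group, a difference at 1 time alone could not pass this adjustment, whatever its size. Since replicate numbers pair the samples, agonist and control arrays of the same number were also compared. The agonist array was higher in 4 of 4 pairs at 4 h, 1 of 4 at 16 h and 4 of 4 at 64 h, and the exact two-sided sign-flip permutation p was 0.125, 1 and 0.125, where 16 sign flips allow no value under 0.125. With the replicate block the standard error was 0.27 and the p at 64 h, adjusted over all genes tested, was 0.0750. A difference at 64 h alone therefore stays open. Leaving out 1 array, which breaks a pair, changed the sign at 4 and 16 h. At 4 h it was -0.02 without control replicate 3 and -0.02 without agonist replicate 4. At 16 h it was -0.10 and -0.45 without control replicates 2 and 3 and -0.09 and -0.13 without agonist replicates 1 and 4.

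At 4 h the comparison of agonist with control asked for the earliest response. The largest differences were in genes of inflammatory cytokines, although no single gene passed the test. TNF encodes tumour necrosis factor, IL6 an interleukin of the acute phase, and IL1B a cytokine that alerts neighbouring cells to damage. All 3 are targets of NF-kB, the transcription factor that starts inflammatory programmes, and its target genes as a group were higher with the agonist.

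In agonist cultures at 4 h, TNF was higher by a log2 value of 2.36 ± 0.50, IL6 by 3.92 ± 0.84 and IL1B by 3.54 ± 0.78, each with all 4 agonist arrays above all 4 control arrays. Their adjusted p was 0.477. The sizes depend on low control signals: all 4 control arrays of IL6 were under 105, and with the highest offset tried IL6 was at 2.38, PTGS2 at 1.24 and TNF at 1.70, where TNF passed (adjusted p = 0.0168). The 3 genes passed when adjusted over the list alone, the list of cytokines and chemokines, of which 0 passed over all genes tested. This list rose as a group: 20 of its 25 members tested had positive fold changes, with a median of 0.39 (camera adjusted p = 5.01e-08), and adjusted p = 0.00159 with an estimated correlation. NF-kB targets rose too, with 29 of 29 members positive and a median of 0.47 (camera adjusted p = 6.46e-15), and adjusted p = 0.00643 with an estimated correlation. Of these targets 0 passed, over all genes or adjusted over the list alone. Among them ICAM1, an adhesion molecule, had a log2 fold change of 1.32 ± 0.39, IER3 of 1.22 ± 0.42, NFKBIZ of 0.81 ± 0.27 and PTGS2, the inducible cyclooxygenase, of 2.02 ± 0.74. The senescence-associated secretory phenotype, the secreted factors of senescent cells, shares IL6, IL1B and ICAM1 with these lists. It had a median of 0.16, with 18 of 26 members positive (camera adjusted p = 1.31e-06) and adjusted p = 0.0290 with an estimated correlation, and these 3 members passed when adjusted over the list alone. Immediate early genes, which respond before new protein is made, were positive in 17 of 17 members with a median of 0.30 (camera adjusted p = 0.00346), with adjusted p = 0.359 with an estimated correlation. That call ended without control replicate 2 (adjusted p = 0.698) or without agonist replicate 1 (adjusted p = 0.225), and the other 3 list calls held without each array. With fry 1 of the 4 list calls passed.

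The remaining 26 lists did not pass at 4 h. Genes of senescence and cytokine release named in advance did not pass after adjustment: CXCL8 2.96 ± 1.18, IFNG 0.92 ± 0.48, NFKBIA 0.89 ± 0.42, CDKN1A -0.30 ± 0.60 and PRKDC, the DNA-dependent protein kinase, -0.02 ± 0.26, all with adjusted p = 0.99992. IER5 at 1.01 ± 0.24 (adjusted p = 0.887) and MLLT11 at 0.83 ± 0.20 (adjusted p = 0.99992) were the other genes with the smallest p. The sign of CDKN1A depended on single arrays, being 0.05 without control replicate 3 and 0.26 without agonist replicate 1. That of PRKDC changed without control replicate 1 (0.02), control replicate 4 (0.01) or agonist replicate 1 (0.13). Over all genes limma called 0, with or without the replicate block. An unadjusted p under 0.05 was found for 204 genes, and for 403 with the block, where chance gives 592. A list's median and mean differed in sign for proliferation and cytotoxic machinery (median positive) and for angiogenesis factors, cholesterol synthesis and platelet markers (median negative). NK transcription factors had a negative median and mean with a test directed upward.

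**Figure D1:**
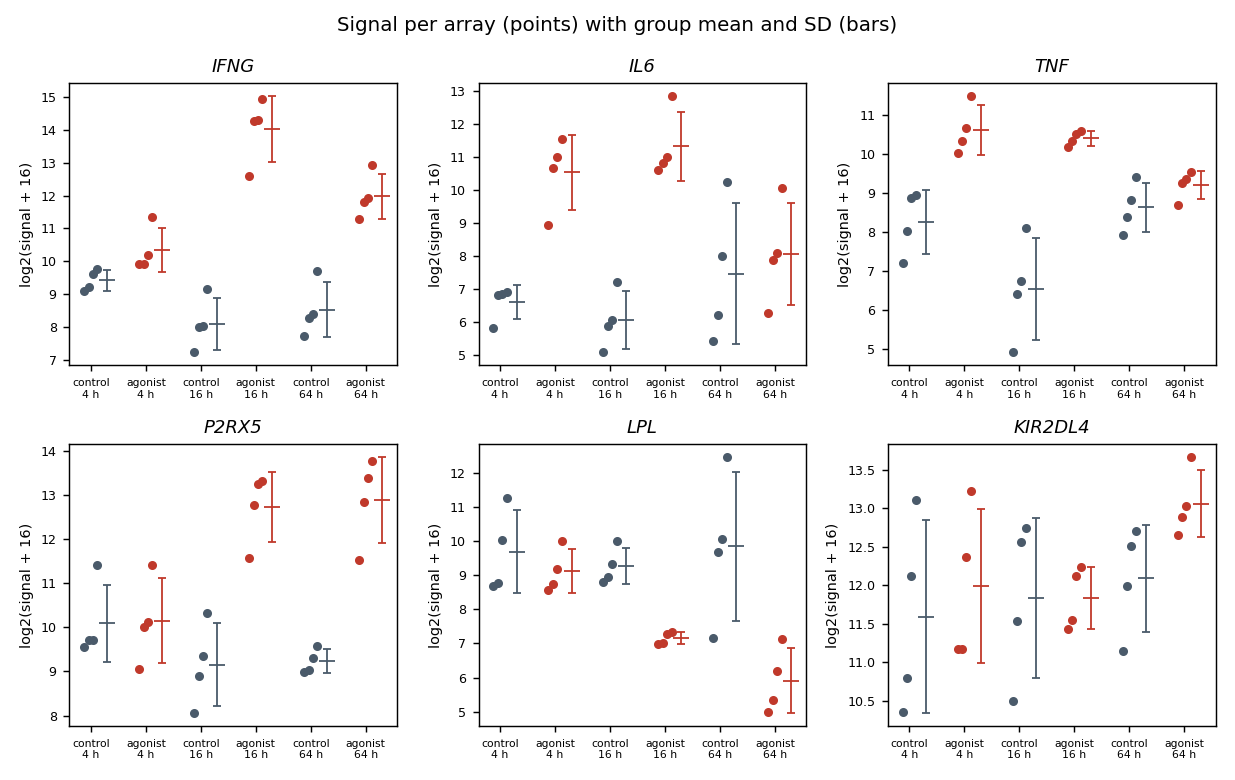
Log2(signal + 16) of IFNG, IL6, TNF, P2RX5, LPL and KIR2DL4 on each array (points) by treatment and time, with group means and SD (bars, n = 4). IFNG was highest in agonist cultures at 16 h (mean 14.03 against 8.10 in control), and LPL was lowest in agonist cultures at 64 h (mean 5.91 against 9.85).

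After 16 h of the agonist the cells expressed a broad inflammatory programme. IFNG, which encodes interferon gamma, the main macrophage-activating cytokine of NK cells, rose most. Also higher than in control cultures of the same time were IL6, IL1B and TNF, the interferon-induced GTPase gene GBP1, and IL2RA, the inducible chain of the interleukin-2 receptor. Genes that fell included MAP2K6, a kinase that activates p38, and SBK1, another kinase gene. NF-kB targets, interferon-stimulated genes and the unfolded protein response rose as groups.

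Of 11844 genes tested at 16 h, 112 passed, 80 higher and 32 lower with the agonist. The balance depended on the scaling: with each array shifted to a common median, 94 were higher and 6 lower, and 82 of the 112 were among them. Of the 10 falls named below, RASSF1-AS1, MAP2K6, SBK1 and GSN passed with that shift and the other 6 did not, with adjusted p from 0.0510 for CCL16 to 0.0966 for DPEP3. IFNG rose by 5.93 ± 0.48 on the log2 scale, a 61.0-fold change (adjusted p = 6.09e-08). IL6 rose by 5.25 ± 0.84 (adjusted p = 0.00178), IL1B by 4.31 ± 0.78 (adjusted p = 0.00529) and TNF by 3.86 ± 0.50 (adjusted p = 0.000211). TNF in agonist arrays lay at log2 values of 10.01 to 11.50 at 4 h and 10.17 to 10.58 at 16 h. In control arrays it lay at 7.21 to 8.96 and 4.91 to 8.11. The larger TNF difference at 16 h thus came with lower control values and not with higher agonist values. Control signals of IL6 and TNF were low, from 17.9 to 133 and from 14.2 to 261, so the sizes depend on the offset. With the highest tried, IL6 was at 3.16, TNF at 2.17, FAM241A at 2.85, DUSP5 at 1.98, RASSF1-AS1 at -1.53 and CCL16 at -0.91, all still called, while GSN was not (-1.13, adjusted p = 0.0574). Further rises were those of FAM241A at 4.45 ± 0.72, PTGS2 at 3.80 ± 0.74, the ATP-gated channel gene P2RX5 at 3.57 ± 0.53, GBP1 at 3.10 ± 0.57, the phosphatase gene DUSP5 at 2.97 ± 0.67 and IL2RA at 2.62 ± 0.50, with adjusted p from 0.000929 for P2RX5 to 0.0285 for DUSP5. The largest falls were those of RASSF1-AS1 at -2.49 ± 0.52 and CXCR3, a chemokine receptor gene, at -2.49 ± 0.61 (adjusted p = 0.0452). The other probe set of CXCR3 gave 0.16. Its call held without agonist replicate 3 and ended without each of the other 7 arrays (highest adjusted p 0.184 without agonist replicate 4), and its log2 fold change was -1.16 with the highest offset tried (adjusted p = 0.0997). It ended with 8 other settings as well, among them an offset of 64, quantile normalization and no filter (CXCR3, agonist vs control at 16 h; adjusted p from 0.0547 to 0.180). MAP2K6 fell by 1.60 ± 0.28 (adjusted p = 0.00378) and the kinase gene SBK1 fell by 1.28 ± 0.21 (adjusted p = 0.00178). NFIA at -1.41 ± 0.35, the actin-severing protein gene GSN at -1.38 ± 0.34, CCL16 at -1.37 ± 0.31, the dipeptidase genes DPEP2 at -1.34 ± 0.28 and DPEP3 at -1.31 ± 0.32, and the tumour suppressor gene RASSF1 at -1.32 ± 0.29 also passed, with adjusted p from 0.0161 for DPEP2 to 0.0483 for NFIA. The 6 other probe sets of GSN ranged from -0.76 to 0.20, 1 of them with the opposite sign. Other probe sets gave smaller changes of the same sign for FAM241A (2.14), GBP1 (1.25 to 2.96), NFIA (-1.30 to -0.55) and SBK1 (-0.66). By the naming rule, each of these 20 genes had all 4 agonist arrays on 1 side of all 4 control arrays. The same held for 106 of the 112 called genes and for 844 of all genes tested, where chance gives 2.86 % for unpaired arrays.

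NF-kB targets rose at 16 h in 29 of 29 members, with a median of 0.83 (camera adjusted p = 3.83e-20); 9 passed over all genes and 14 adjusted over the list alone. MAP3K8, a kinase upstream of ERK, rose by 1.48 ± 0.24, NFKBIZ by 1.58 ± 0.27, GADD45B by 1.69 ± 0.30 and the inhibitor gene NFKBIA by 1.75 ± 0.42 (adjusted p = 0.0407). Interferon-stimulated genes had a median of 0.78, 23 of 27 positive (camera adjusted p = 8.92e-11), with 4 members called over all genes and 12 adjusted over the list alone. GBP1, the cytokine-signalling brake SOCS1 at 2.29 ± 0.47, EPSTI1 at 2.07 ± 0.44 and GBP2 at 0.78 ± 0.19 were called. The unfolded protein response was positive in 16 of 16 members with a median of 0.52 (camera adjusted p = 3.20e-07), with 1 member called over all genes and 1 adjusted over the list alone. This was the endoplasmic reticulum chaperone gene HSPA5, which rose by 0.78 ± 0.17 (adjusted p = 0.0243). Antigen processing had a median of 0.45 (camera adjusted p = 5.66e-06), with 2 members called, PSME1 at 0.75 ± 0.17 and PSMB8 at 0.66 ± 0.15, and 5 adjusted over the list alone. Activation markers and cytokine receptors had a median of 0.63 (camera adjusted p = 2.70e-05), with 5 higher and 1 lower, and 7 and 1 adjusted over the list alone. CD38, an ectoenzyme of activated lymphocytes, rose by 1.67 ± 0.27, IL15RA by 2.42 ± 0.45 and IL18R1 by 1.48 ± 0.31 (adjusted p = 0.0183). Cytokines and chemokines had a median of 0.58 (camera adjusted p = 2.70e-05), with 4 members called and 6 adjusted over the list alone. These 6 lists also passed with an estimated correlation, with adjusted p from 0.00275 for NF-kB targets to 0.0459 for antigen processing.

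A further 9 lists passed at 16 h with the preset correlation and not with an estimated one. The senescence-associated secretory phenotype had a median of 0.50 with 4 members called higher (6 higher and 2 lower adjusted over the list alone) and camera adjusted p = 0.00567, but adjusted p = 0.172 with an estimated correlation. Ribosome biogenesis had a median of 0.36 with the helicase gene DDX21 up by 1.27 ± 0.24 (camera adjusted p = 0.00340), apoptosis inhibitors a median of 0.25 with 0 members called (camera adjusted p = 0.0430) and NK transcription factors a median of 0.01 (camera adjusted p = 0.0368), each with adjusted p = 0.172 with an estimated correlation. Among the NK transcription factors 2 were called, IRF8 at 1.94 ± 0.28 and BHLHE40 at 1.18 ± 0.27. Adjusted over the list alone, 1 ribosome biogenesis gene, 1 apoptosis inhibitor, 3 NK transcription factors, 3 heat shock genes, 0 glycolysis genes, 2 cholesterol synthesis genes, 2 immediate early genes and 3 cytotoxic machinery genes passed. Heat shock genes had a median of 0.43 with 0 called over all genes (camera adjusted p = 0.00361), with adjusted p = 0.0706 with an estimated correlation. Glycolysis and hypoxia genes were positive in 18 of 19 members with a median of 0.34 and 0 called (camera adjusted p = 0.00523), with adjusted p = 0.437 with an estimated correlation. Cholesterol synthesis had a median of 0.22 with MSMO1 up by 1.09 ± 0.22 (camera adjusted p = 0.0215), with adjusted p = 0.184 with an estimated correlation. Immediate early genes had a median of 0.35 with DUSP5 called (camera adjusted p = 0.0157), with adjusted p = 0.267 with an estimated correlation. Cytotoxic machinery, the genes of target cell killing, had a median of 0.13 with the death ligand gene TNFSF10 up by 1.36 ± 0.19 (camera adjusted p = 0.0236), with adjusted p = 0.399 with an estimated correlation.

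Beside the secretory phenotype, the other lists tied to senescence and that of vascular remodelling did not pass at 16 h: p53 targets (median -0.15, camera adjusted p = 0.971), cell cycle inhibitors and senescence markers (median -0.04, 0.430), the DNA damage response (median 0.20, 0.114), proliferation (median -0.11, 0.971) and angiogenesis and vascular remodelling factors (median -0.07, 0.585). Members under the filter or without a probe set assigned to them alone were not tested. Among them were VEGFC, ANGPT1, HGF and MMP2 of the vascular list, and GLB1, CDKN2B and CDKN2C of the senescence markers. The secretory phenotype lacked CCL3, CSF2, AREG and SERPINE1, among others. The senescence markers include LMNB1, which senescent cells lose, beside CDKN1A, so a shift of that list in 1 direction does not measure senescence. CDKN1A, the cyclin-dependent kinase inhibitor p21, had a log2 fold change of 1.53 ± 0.60 (adjusted p = 0.311) and PRKDC of 0.42 ± 0.26 (adjusted p = 0.599). CXCL8 at 3.56 ± 1.18 had adjusted p = 0.193, and 0.00186 with the replicate block. TIMP1, an inhibitor of matrix metalloproteinases, had -1.63 ± 0.50 (adjusted p = 0.152), and 0.0331 with the replicate block. With the highest offset tried TIMP1 was at -0.71 (adjusted p = 0.233). Among lists that did not pass, PMAIP1, a promoter of apoptosis, rose by 1.67 ± 0.34, the cyclin gene CCND2 by 0.92 ± 0.20 and the checkpoint receptor gene HAVCR2 by 1.70 ± 0.36, while CD160 fell by 0.92 ± 0.16 and KLRG1 fell by 0.89 ± 0.19. With each array shifted to a common median, CD160 had adjusted p = 0.0512 and KLRG1 0.104. Also not called were apoptosis promoters (median -0.00041, camera adjusted p = 0.430), NK cell receptors and adaptors (-0.04, 0.514) and metallothioneins (0.39, 0.137, and 0.0447 with the replicate block). Nor were markers of monocytes (-1.13, 0.225), B cells (-0.16, 0.891), T cells (-0.14, 0.781), dendritic cells (-0.03, 0.971), platelets (-0.32, 0.257), erythroid cells (1 gene, -0.16, 0.971) and neutrophils (-0.51, 0.514). The mean was positive against a negative median for p53 targets, cell cycle inhibitors, angiogenesis factors and apoptosis promoters. The test for cell cycle inhibitors was directed upward and those for p53 targets and angiogenesis factors downward.

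With the replicate block 590 genes passed at 16 h, 324 higher and 266 lower, among them all 112. Without control replicates 1, 2, 3 or 4 the count was 62, 36, 58 or 87, and without agonist replicates 1, 2, 3 or 4 it was 95, 44, 101 or 43. Of the 45 genes called at 16 h and named by rule or as leading list members, 20 held without each array, among them IFNG, IL6, IL1B, TNF, PTGS2, P2RX5, GBP1, IL2RA, FAM241A, MAP2K6, SBK1, CD38, IRF8, CD160 and TNFSF10. Leaving out control replicate 1, 2, 3 or 4 ended 12, 24, 17 or 11 of the 45 calls and agonist replicate 1, 2, 3 or 4 ended 15, 22, 11 or 19, with a highest adjusted p of 0.198 for GSN without agonist replicate 2. The list calls that ended were cytotoxic machinery (highest adjusted p 0.114 without control replicate 3), immediate early genes (0.111), apoptosis inhibitors (0.247) and glycolysis and hypoxia (0.225) without control replicate 2, cholesterol synthesis (0.0915) without agonist replicate 1, and NK transcription factors (0.0922) without control replicate 3. The ratio of 3' to 5' ACTB probe sets, a measure of RNA integrity, was 19.8 ± 6.59 in control and 10.6 ± 2.06 in agonist arrays at 16 h (SD, n = 4; exact permutation p = 0.0286, the smallest possible, and adjusted exact p = 0.171 over 6 tests). A difference in 1 of the 6 tests alone could not pass that adjustment. The arrays did not overlap, at 14.6 to 29.3 in control and 7.70 to 12.6 with the agonist. The GAPDH ratio was 1.28 ± 0.22 and 1.13 ± 0.29 (exact permutation p = 0.457). An effect of RNA integrity on the calls at 16 h was not tested and cannot be told apart from that of the agonist.

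**Figure D2:**
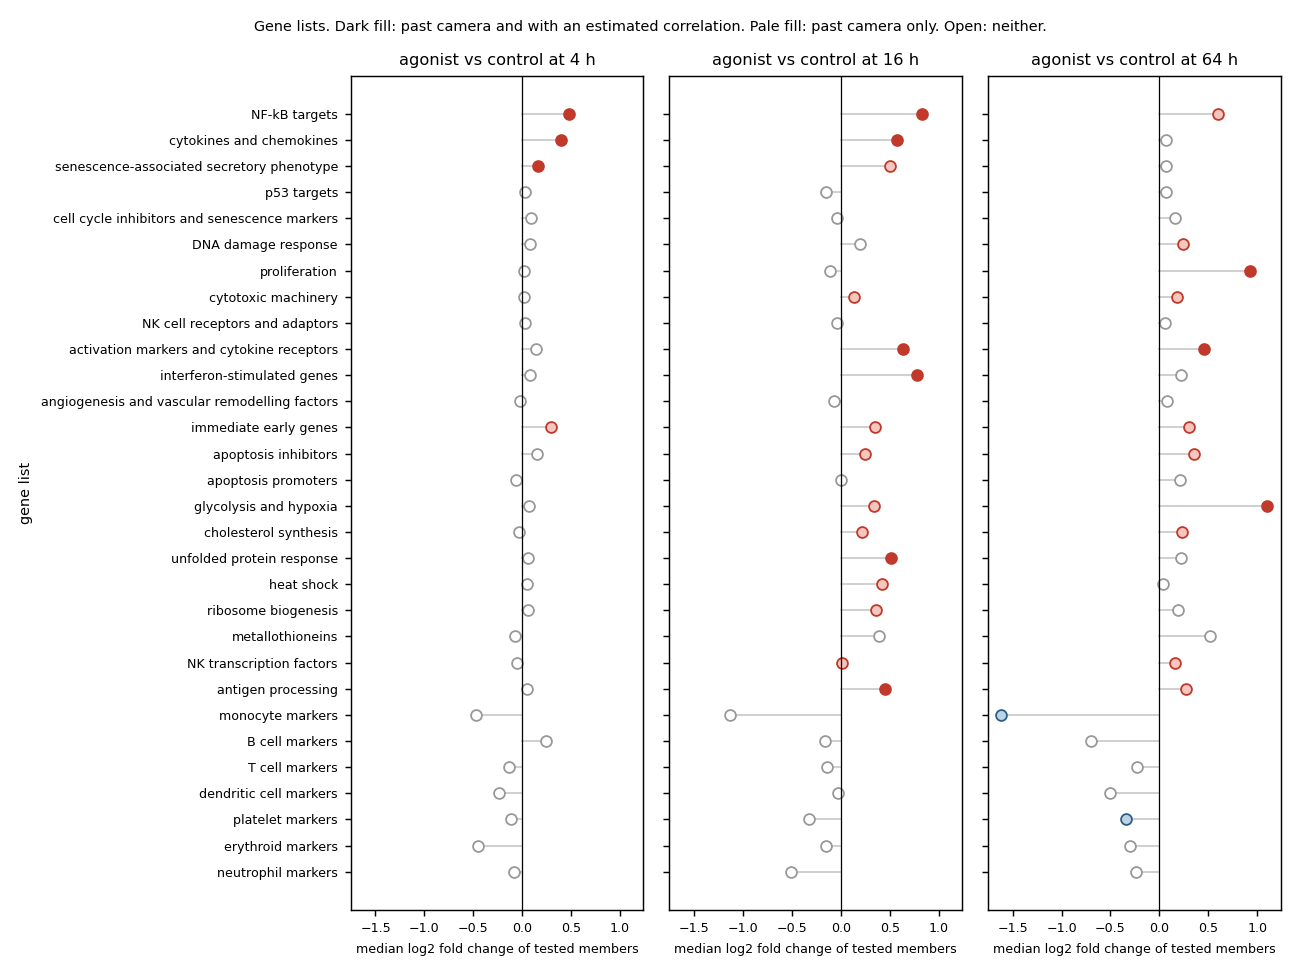
Median log2 fold change, agonist against control, of the members of 30 gene lists at 4, 16 and 64 h. Dark points passed camera with the preset and with an estimated correlation, pale points with the preset one only, and open points with neither; NF-kB targets had medians of 0.47, 0.83 and 0.60.

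At 64 h IFNG was still higher with the agonist, and with it stood genes of metabolism and cell division. Glycolysis genes, which cells use to make energy without oxygen, and proliferation genes, which serve chromosome copying and mitosis, rose as groups. HIF1A, the oxygen-regulated transcription factor, rose with VDR, the vitamin D receptor, and with ENTPD1 (CD39), an enzyme that breaks down extracellular ATP. LPL, lipoprotein lipase, and MSR1, a scavenger receptor, both typical of macrophages, fell.

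Of 11844 genes tested at 64 h, 20 passed, 17 higher and 3 lower with the agonist. P2RX5 rose by 3.66 ± 0.53 (adjusted p = 0.00220), a 12.6-fold change, and IFNG by 3.46 ± 0.48 (adjusted p = 0.00189). VDR rose by 2.58 ± 0.49, SOCS1 by 2.33 ± 0.47, ENTPD1 by 2.11 ± 0.39 and HAVCR2 by 1.73 ± 0.36, with adjusted p from 0.0214 for VDR to 0.0410 for HAVCR2. HIF1A rose by 1.72 ± 0.27 (adjusted p = 0.00557), the mitotic spindle gene NUSAP1 by 1.63 ± 0.33 (adjusted p = 0.0351), EPOP by 1.63 ± 0.31 and SETBP1 by 1.59 ± 0.33. LPL fell by 3.94 ± 0.73 and MSR1 fell by 3.25 ± 0.62 (adjusted p = 0.0214 for both). With the highest offset tried LPL was at -2.11 (adjusted p = 0.136) and MSR1 at -2.14 (adjusted p = 0.0161), and SETBP1 did not pass (1.32, adjusted p = 0.0672). SBK1 fell by 1.26 ± 0.21 (adjusted p = 0.00720). Other probe sets gave smaller changes of the same sign for VDR (0.08 to 1.83), SOCS1 (0.42 to 1.43), LPL (-1.76) and SBK1 (-0.73), those of MSR1 ranged from -3.51 to -1.02, and those of ENTPD1 from 2.39 to 3.70. In 19 of the 20 called genes, and in 443 of all genes tested, the agonist and control arrays did not overlap, where chance gives 2.86 % for unpaired arrays. TNF at 0.57 ± 0.50 (adjusted p = 0.964), CDKN1A at 0.93 ± 0.60 (adjusted p = 0.929), CXCL8 at 1.46 ± 1.18, NFKBIA at 0.65 ± 0.42, PRKDC at 0.23 ± 0.26 (adjusted p = 0.987) and IL6 at 0.60 ± 0.84 (adjusted p = 0.995) did not pass. IL6 was negative without control replicate 1 (-0.08) or agonist replicate 3 (-0.06), and PRKDC without control replicate 1 (-0.0030).

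Glycolysis and hypoxia genes were higher at 64 h in 19 of 19 members with a median of 1.10 (camera adjusted p = 4.18e-20); 2 members passed over all genes and 14 adjusted over the list alone. GPI rose by 1.56 ± 0.32 and ALDOC by 1.48 ± 0.31, both glycolytic enzymes (adjusted p = 0.0410). TPI1 at 1.35 ± 0.33 had adjusted p = 0.148, and 0.000575 with the replicate block. Proliferation genes were higher in 25 of 25 members with a median of 0.93 (camera adjusted p = 1.66e-19); 1 member, NUSAP1, passed over all genes and 13 adjusted over the list alone. TOP2A, the topoisomerase of dividing cells, at 3.10 ± 0.70 had adjusted p = 0.0814, and 0.00432 with the replicate block, and BIRC5 at 3.21 ± 0.77 had adjusted p = 0.145, and 0.0261 with the block. Activation markers and cytokine receptors had a median of 0.46, 18 of 21 positive (camera adjusted p = 4.16e-05), with 0 members called over all genes and 3 adjusted over the list alone; IL2RA at 2.21 ± 0.50 had adjusted p = 0.0814, and 0.00115 with the block. These 3 lists also passed with an estimated correlation, each with adjusted p = 0.0408.

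A further 10 lists passed at 64 h with the preset correlation only. NF-kB targets were positive in 24 of 29 members with a median of 0.60 (camera adjusted p = 6.16e-08), with adjusted p = 0.0525 with an estimated correlation; 1 member passed over all genes, MAP3K8 at 1.34 ± 0.24 (adjusted p = 0.0201), and 5 adjusted over the list alone. Monocyte markers were lower in 4 of 4 members tested with a median of -1.62 (camera adjusted p = 0.000735), with adjusted p = 0.0622 with an estimated correlation. Of these, 0 passed over all genes and 1 adjusted over the list alone. Other members, among them CD14, S100A8, FCN1 and CD163, lay under the filter and were not tested. In control cultures the list rose between 4 and 64 h with the preset correlation (below), so a level under control is not by itself a fall over time. CSF1R, the receptor of a macrophage growth factor, had -1.52 ± 0.49, MNDA -1.71 ± 0.75, CLEC7A -1.15 ± 0.67 and LYZ -2.10 ± 1.39. Platelet markers fell with a median of -0.35 (camera adjusted p = 0.0256), with adjusted p = 0.156 with an estimated correlation, and TREML1 at -1.79 ± 0.61 passed adjusted over the list alone. With the highest offset tried TREML1 was at -0.85. Cytotoxic machinery had a median of 0.18 (camera adjusted p = 0.00150), with adjusted p = 0.211 with an estimated correlation, and TNFSF10 rose by 0.98 ± 0.19 (adjusted p = 0.0233). NK transcription factors had a median of 0.16 (camera adjusted p = 0.0409), with adjusted p = 0.197 with an estimated correlation, and BHLHE40 rose by 1.51 ± 0.27 (adjusted p = 0.0201). Immediate early genes (median 0.31, camera adjusted p = 0.0155), the DNA damage response (median 0.24, 0.0495) and cholesterol synthesis (median 0.23, 0.0263) each had adjusted p = 0.211 with an estimated correlation. Antigen processing (median 0.27, camera adjusted p = 0.0243) had adjusted p = 0.236 with an estimated correlation, and apoptosis inhibitors (median 0.36, 0.0263) adjusted p = 0.160 with an estimated correlation; no member of these 5 lists passed over all genes or adjusted over the list alone.

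Lists of the study's subject that did not pass at 64 h were the senescence-associated secretory phenotype (median 0.07, camera adjusted p = 0.607), p53 targets (0.06, 0.806), cell cycle inhibitors and senescence markers (0.16, 0.0932) and angiogenesis and vascular remodelling factors (0.08, 0.975, with the test directed downward). As at 16 h, members under the filter or without a probe set assigned to them alone were not part of these tests. VEGFA, the vascular endothelial growth factor, at 2.25 ± 0.73 had adjusted p = 0.390, and 0.0253 with the replicate block, and NRP2, a co-receptor for it, was at -1.57 ± 0.68 (adjusted p = 0.696). LMNB1, the nuclear lamin lost in senescent cells, at 1.48 ± 0.36 had adjusted p = 0.148, and 0.00111 with the block, and the death receptor gene FAS at 1.17 ± 0.32 had adjusted p = 0.206, and 0.0480 with the block. The positive value of LMNB1 moves the list of senescence markers upward, although senescent cells lose LMNB1. The remaining lists not called were cytokines and chemokines (0.07, 0.371), NK cell receptors and adaptors (0.06, 0.178), apoptosis promoters (0.21, 0.189), heat shock (0.03, 0.694), ribosome biogenesis (0.19, 0.271). Nor did markers of B cells (-0.70, 0.0901), T cells (-0.23, 0.427), dendritic cells (-0.50, 0.271), erythroid cells (-0.30, 0.724) and neutrophils (-0.24, 0.692) pass. Interferon-stimulated genes (0.23, 0.0522), the unfolded protein response (0.22, 0.0512) and metallothioneins (0.52, 0.0546) did not pass, but had adjusted p of 0.0415, 0.0292 and 0.0153 with the replicate block.

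With the replicate block 179 genes passed at 64 h, 115 higher and 64 lower. Without control replicates 1, 2, 3 or 4 the count was 3, 10, 5 or 30, and without agonist replicates 1, 2, 3 or 4 it was 2, 13, 29 or 8. Of 18 named genes called, P2RX5 and IFNG held without each array. Without all 6 arrays of replicate 1 no gene passed in the fit without a block. P2RX5 was at 3.39 (adjusted p = 0.237) and IFNG at 3.39 (adjusted p = 0.149). This setting was not run with the block, so whether calls of the paired fit depend on replicate 1 was not tested. Control replicate 1, 2, 3 or 4 ended 15, 9, 14 or 2 of the calls when left out and agonist replicate 1, 2, 3 or 4 ended 16, 8, 1 or 10. The highest adjusted p was 0.261 for ALDOC without agonist replicate 1, where HIF1A had 0.0543 and LPL 0.0873, and MSR1 had 0.117 without control replicate 2. Of the list calls, those of NF-kB targets, proliferation, activation markers, glycolysis and hypoxia, and monocyte markers held without each array. The others ended: immediate early genes (0.0556), apoptosis inhibitors (0.0871), cholesterol synthesis (0.288) and antigen processing (0.117) at the highest without agonist replicate 1, cytotoxic machinery (0.0637) without agonist replicate 2, and the DNA damage response (0.213), NK transcription factors (0.269) and platelet markers (0.213) without control replicate 1.

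The agonist effects were then compared between times. Between 4 and 16 h the effect on IFNG grew. The effect on the cytokine list was lower at 64 h than at 16 h by camera, but did not pass by fry. NK cells keep IFNG open for rapid transcription. The interaction test found 1 gene whose effect differed between 4 and 16 h, IFNG, by 5.01 ± 0.68 (adjusted p = 0.00128), and it held without each array (highest adjusted p 0.00612). Without all 6 arrays of replicate 1 the difference was 4.44 and did not pass (adjusted p = 0.188). The count was 3 without control replicate 2 at 16 h, and 2 without control replicate 4 at 4 h or agonist replicate 1 or 4 at 16 h. With the replicate block it was 27, 18 higher and 9 lower at 16 h. Between 16 and 64 h limma called 0 genes, with a smallest adjusted p of 0.99906. An unadjusted p under 0.05 was found for 414 genes, where chance gives 592, and for 912 with the replicate block. With the block 4 genes passed, GBP1, GBP4, GCH1 and MARCKS, with lower effects at 64 h and named after their values were seen. The smallest p without the block belonged to TNF at -3.28 ± 0.71, GBP4 at -1.41 ± 0.32 (0.00991 with the block), the histone gene H2BC5 at 1.59 ± 0.39, IL6 at -4.65 ± 1.18 and LACTB at -1.09 ± 0.29. With the highest offset tried TNF was at -1.80 and IL6 at -3.00. TNF in control arrays lay at log2 values of 4.91 to 8.11 at 16 h and 7.93 to 9.40 at 64 h. In agonist arrays it lay at 10.17 to 10.58 and 8.69 to 9.53, so both sides moved. Between 4 and 64 h limma called 0, with or without the block. An unadjusted p under 0.05 was found for 365 genes, and for 848 with the block. The smallest adjusted p was 0.797 for P2RX5 at 3.61 ± 0.75. Next by p were CKS2 at 1.83 ± 0.45, TREML1 at -3.49 ± 0.86, TNFSF10 at 1.07 ± 0.27 and IFNG at 2.54 ± 0.68. With the highest offset tried TREML1 was at -1.76.

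Among lists, cytokines and chemokines had a lower effect at 64 h than at 16 h, with a median of -0.44 (camera adjusted p = 0.000152) and adjusted p = 0.0444 with an estimated correlation. This list did not pass with fry. Proliferation had a higher effect at 64 h than at 16 h, with a median of 1.16 (camera adjusted p = 2.14e-13), but adjusted p = 0.167 with an estimated correlation, and glycolysis and hypoxia likewise with 0.68 (camera adjusted p = 1.40e-06), but adjusted p = 0.251 with an estimated correlation, and camera adjusted p = 0.184 without all 6 arrays of replicate 1. Across genes, which are not independent replicates, the log2 fold changes at 16 and 64 h had Pearson's r = 0.352 and Spearman's rho = 0.315, those at 4 and 16 h 0.175 and 0.12, and those at 4 and 64 h 0.0808 and 0.0613. The comparisons at the 3 times share no arrays. They do share each gene's estimate of spread and the replicate numbers, so their calls are not independent. Called at both 16 and 64 h were 11 genes higher and 1 lower, where independent calls would give 0.115 and 0.00811, and none in opposite directions; with the replicate block the numbers were 47 and 29. Of the 112 genes called at 16 h, 111 had the same sign at 64 h, and of the 20 called at 64 h, 19 had the same sign at 16 h. The exception was NUSAP1, at -0.10 at 16 h. Without all 6 arrays of replicate 1 no gene was called at 64 h, so no call could be shared.

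**Figure D3:**
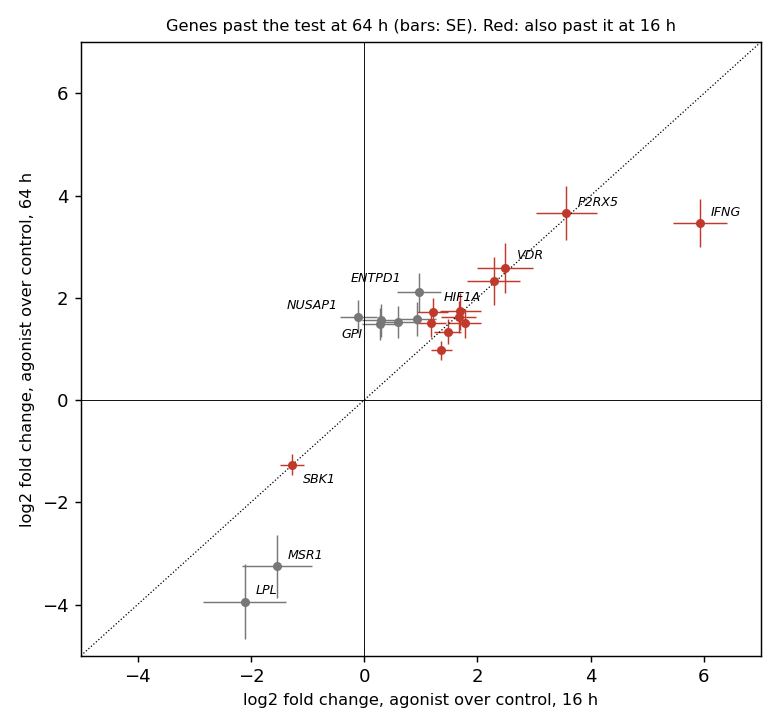
Log2 fold change, agonist against control, at 16 h (horizontal) and 64 h (vertical) of the 20 genes called at 64 h, with standard errors as bars and the line of equality dotted; red points were also called at 16 h. P2RX5 had 3.57 and 3.66, and LPL -2.11 and -3.94.

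The control cultures were compared over time, since changes without the agonist are the background of its effect. Glycolysis and hypoxia genes rose between 4 and 16 h. PFKP, ALDOC, ENO2 and ALDOA encode enzymes that break down glucose, and MIR210HG is the host of a microRNA induced when oxygen is low. Of all genes tested, 10 passed at 16 h against 4 h, 9 higher and 1 lower, and in all 10 the arrays did not overlap. PPFIA4 rose by 3.67 ± 0.59, ENO2 by 2.26 ± 0.37, ALDOC by 1.94 ± 0.31, PFKP by 1.75 ± 0.26 (adjusted p = 0.00479), MIR210HG by 1.69 ± 0.34 and ALDOA by 1.31 ± 0.25, and SKIL fell by 1.31 ± 0.21. The other probe set of PFKP gave 0.85, and those of SKIL ranged from -1.13 to -0.16. With the replicate block 139 genes passed. The count was 1, 22, 10 or 4 without control replicates 1, 2, 3 or 4 at 16 h and 6, 7, 6 or 17 without those at 4 h. Without all 6 arrays of replicate 1, 3 passed, PFKP and SKIL among them. PFKP held without each array, while PPFIA4, ALDOC and SKIL ended without control replicate 1 at 16 h (adjusted p = 0.0512), where ENO2 reached 0.0705, MIR210HG 0.210 and ALDOA 0.161.

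Glycolysis and hypoxia genes were higher at 16 h than at 4 h in 19 of 19 members in control cultures, with a median of 1.21 (camera adjusted p = 1.74e-29) and adjusted p = 0.0107 with an estimated correlation; 3 passed over all genes and 17 adjusted over the list alone. Interferon-stimulated genes fell, with a median of -0.62 and 2 of 27 positive (camera adjusted p = 1.89e-07), but adjusted p = 0.230 with an estimated correlation. NF-kB targets (median -0.28, camera adjusted p = 0.00780), activation markers (-0.27, 0.0181), heat shock (-0.44, 0.0144) and antigen processing (-0.18, 0.0332) passed downward with the preset correlation only, with adjusted p = 0.574, 0.343, 0.230 and 0.634 with an estimated correlation. These last 4 calls ended without single arrays, with a highest adjusted p of 0.126 for NF-kB targets and 0.188 for activation markers without control replicate 2 at 16 h, 0.145 for heat shock without control replicate 2 at 4 h and 0.117 for antigen processing without control replicate 1 at 4 h.

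Between 4 and 64 h in control cultures 1 gene passed, C1orf162, which rose by 1.62 ± 0.20 (adjusted p = 0.000197) and held without each array (highest adjusted p 0.00251). This comparison shares the control arrays at 64 h with the agonist comparison and those at 4 h with the other control comparison. The count was 4 without control replicate 2 at 4 h, and 2 and 3 without control replicates 2 and 4 at 64 h, and 243 with the replicate block. NF-kB targets (median -0.48, camera adjusted p = 0.000316), activation markers (-0.34, 0.00165) and interferon-stimulated genes (-0.34, 0.000382) fell, and monocyte markers (1.33, 0.00876) and the senescence-associated secretory phenotype (0.44, 0.0106) rose, each with adjusted p = 0.279 with an estimated correlation. Proliferation genes fell (-0.24, 0.0106), with adjusted p = 0.562 with an estimated correlation. Without control replicate 2 at 4 h the calls of the secretory phenotype (0.161) and of monocyte markers (0.0671) ended, and proliferation ended without control replicate 4 at 4 h (0.0981).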

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

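Chosen only after their results were seen were the 3 tests of the macrophage-associated genes, the tests of RNA degradation and of T cell outgrowth, the list tests without single arrays, the splits of the interactions within pairs, and the counts of other splits for agonist against control at 4 h and for the effect at 64 h minus that at 16 h and at 4 h.

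Genes typical of macrophages were lower with the agonist at 64 h, LPL and MSR1 by -3.94 and -3.25 and the 4 tested members of the monocyte marker list by a median of -1.62. A lower share of every other cell type in the agonist cultures cannot be told apart: all 6 other marker lists had a negative median (B cells -0.70, dendritic cells -0.50, platelets -0.35, erythroid cells -0.30, neutrophils -0.24, T cells -0.23), and of the 4 lists with 3 or more members 2 differed from the monocyte list by more than 2 SE over arrays (T cells by 1.43 ± 0.39, exact permutation p = 0.0286; dendritic cells by 1.24 ± 0.55), while B cells at 0.98 ± 0.55 and platelets at 1.02 ± 0.69 did not. Fewer monocytes or macrophages in the agonist cultures may explain the falls and cannot be told apart from lower expression within cells. In a list of 17 macrophage markers without LPL and MSR1, drawn up after these falls had been seen, 14 of 15 measured were below 0 with a median of -0.78, and their mean log2 value differed by -0.88 ± 0.33 (8.13 ± 0.61 in control, 7.25 ± 0.27 in agonist, SD, n = 4; exact permutation p = 0.0571), with CTSD the most abundant of the 3 that passed the filter at 11.07 in control and 10.51 in agonist. The exact permutation tests of the marker lists ignore the pairs by replicate number. A fall of signals near the array's floor (median percentile of the markers and called genes 45.2 in control, called falls 62.1 or above; with the highest offset LPL was at -2.11 with adjusted p = 0.136) and a response of the cells to the agonist stay open, and the labels name no sort that would remove macrophages.

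Replicate 1 stood apart on the first principal component of the arrays, which held 18.1 % of the variance: its 6 arrays lay between -49.0 and -36.9 and the other 18 between 0.780 and 23.1. In the groups at 64 h this put an array far from the others, at -42.1 in control (others 13.5 to 23.1) and at -49.0 with the agonist (others 12.02 to 14.4). The scaling or distribution of the signals as the whole cause is argued against by quantile normalization, after which the gap was 39.9 (37.7 before) and the range of the other arrays 18.6. A difference in RNA degradation stays open and cannot be told apart, since replicate 1 had the lowest ACTB ratio of 3' to 5' signal in 5 of 6 groups but the lowest GAPDH ratio in 0 and the highest in 1. The labels do not say what a replicate number stands for, so no biological explanation was tested.

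Proliferation genes were higher with the agonist at 64 h in 25 of 25 members, with a median of 0.93. A single replicate number as the source is argued against by the medians with each number left out, from 0.68 to 1.39. The shape of the signal distribution is argued against by quantile normalization, which gave 0.99. Outgrowth of T cells cannot be told apart. The T cell markers had a median of -0.23, against a bound of 0.23 taken from the proliferation median. The standard error of this median was 0.29, taken over the 8 member genes and not over arrays. A higher rate of division of NK cells under the agonist stays possible and was not tested.

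Of 176 groups of 4 values tested, 13 had an array far from the other 3, where chance gives about 5 %; 11 were genes and 2 the component above. At 4 h in control, IL6 had an array at 5.82 (others 6.83 to 6.92), MLLT11 at 10.45 (others 9.95 to 10.01), NFKBIA at 14.43 (others 12.84 to 12.99) and P2RX5 at 11.41 (others 9.55 to 9.71). At 16 h PTGS2 had an array at 7.23 in control (others 7.51 to 7.55) and at 13.40 with the agonist (others 10.48 to 10.67), IL1B at 14.95 with the agonist (others 12.29 to 12.60), DUSP5 at 5.72 in control (others 8.24 to 8.64) and RASSF1-AS1 at 11.10 in control (others 9.77 to 9.85). At 64 h HIF1A had an array at 11.92 in control (others 12.33 to 12.41) and CXCL8 at 15.01 with the agonist (others 10.67 to 10.88).

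The agonist effect on IFNG differed between 16 and 4 h by 5.01 on the log2 scale by the interaction test. The effect on 7 lists was higher at 16 h than at 4 h with the preset correlation and none with an estimated one. Their medians, with the adjusted p under the preset and the estimated correlation, were 0.39 for NF-kB targets (4.64e-05, 0.174), 0.41 for activation markers and cytokine receptors (0.00493, 0.174), 0.60 for interferon-stimulated genes (1.99e-06, 0.174), 0.48 for the unfolded protein response (4.64e-05, 0.174), 0.35 for heat shock (0.0332, 0.216), 0.19 for ribosome biogenesis (0.0406, 0.426) and 0.39 for antigen processing (0.000434, 0.174). The calls of heat shock and ribosome biogenesis ended without some arrays, with a highest adjusted p of 0.188 without agonist replicate 3 at 4 h and 0.170 without control replicate 2 at 16 h.

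Between 16 and 64 h the effect on 9 lists differed with the preset correlation, and 1 of them, cytokines and chemokines, with an estimated one. None of the 9 passed with fry. Higher at 64 h were proliferation, with a median of 1.16, and glycolysis and hypoxia, with 0.68. Lower at 64 h were cytokines and chemokines with -0.44 (adjusted p = 0.000152, and 0.0444 with an estimated correlation), NF-kB targets with -0.48 (4.22e-06, 0.174), the senescence-associated secretory phenotype with -0.32 (0.0201, 0.338), interferon-stimulated genes with -0.43 (3.70e-06, 0.174), the unfolded protein response with -0.29 (0.00143, 0.174), heat shock with -0.37 (0.0147, 0.174) and antigen processing with -0.20 (0.0167, 0.369). The calls of 3 lists ended without some arrays: the secretory phenotype reached at most 0.157 without agonist replicate 4 at 64 h, heat shock 0.0520 without agonist replicate 1 at 16 h and antigen processing 0.221 without agonist replicate 3 at 16 h.

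Between 4 and 64 h the effect on 8 lists differed with the preset correlation and on none with an estimated one. Higher at 64 h were proliferation with a median of 1.11 (3.36e-14, 0.151 estimated), glycolysis and hypoxia with 0.96 (4.49e-13, 0.151), cytotoxic machinery with 0.18 (0.0182, 0.312) and activation markers and cytokine receptors with 0.38 (0.0303, 0.284). Lower at 64 h were cytokines and chemokines with -0.25 (0.0303, 0.239), the senescence-associated secretory phenotype with -0.30 (0.0303, 0.309), monocyte markers with -1.23 (0.0361, 0.284) and platelet markers with -0.23 (0.0361, 0.268; 0.0589 with the replicate block). Proliferation and glycolysis held without each array; at the highest, cytokines reached 0.151, the secretory phenotype 0.201 and monocyte markers 0.157 without control replicate 2 at 4 h, cytotoxic machinery 0.140 without agonist replicate 2 at 64 h, activation markers 0.165 without agonist replicate 1 at 64 h and platelet markers 0.265 without control replicate 1 at 64 h.

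Signals outside the gene comparisons came from probe sets assigned to no gene or to several: 26 passed at 16 h (14 with no gene and 12 with several), 3 at 64 h and 1 in control at 16 h against 4 h.

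Other splits of the same arrays were counted for each comparison. Over all 35 splits, which ignore the pairs, the real split of agonist against control at 16 h gave 112 genes and the highest of the others 0. At 64 h it was 20 against 1, and for control at 16 h against 4 h 10 against 1 (1 of 35 each). Because replicate numbers pair the samples, shares among all 35 splits cannot exclude chance. Among the 8 splits that part all pairs the highest other was 0 in each, and 8 are too few for a share under 0.05. Where the real count was 0, every split gives as many and the count says nothing about chance: this holds for agonist against control at 4 h (35 of 35 splits, highest other 52) and for the interactions of 64 and 16 h (100 of 100, highest other 3) and of 64 and 4 h (100 of 100, highest other 4). The 52 came from a split that kept pairs of the same replicate number on 1 side and points to the structure by replicate number, since the highest count among the splits that part all pairs was 0. For control at 64 h against 4 h the real split gave 1 and the highest other 1 (2 of 35 splits), so the 35 splits alone do not exclude chance. That other split kept a pair of the same number on 1 side; the highest of the others that part all pairs was 0, and these 8 are too few for a share under 0.05. For the interaction of 16 and 4 h the 100 splits alone do not exclude chance either, with 1 against 12 (7 of 100), but they ignore the pairs. When agonist and control were exchanged within pairs instead, 14 of 100 splits gave as many (highest other 14). All of these but the real one were among the 23 that left every pair at 4 h or at 16 h as it was or exchanged them all, and so carry the agonist effect of that time. The other 76 gave 0. With the replicate block 14 of 100 splits gave at least the real count of 27, with a highest other of 192 among the 23. Among the other 76 the highest was 1. With the replicate block and only the 8 splits that part all pairs, the real counts were 590, 179, 139 and 243 for agonist at 16 h, at 64 h and control at 16 h and 64 h, and the highest others 0, 0, 0 and 1.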

How the results depend on the processing

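Chosen after seeing the data were the highest offset tried, leaving out all 6 arrays of replicate 1, leaving out each replicate number from the similarity, the list tests without single arrays and the sign-flip test of KIR2DL4. The mean difference of that test is that of the fit by construction. It passed at no time and could not, since its smallest possible p is 0.125. Over all settings, values of called genes kept their direction in each case, 1296 past the threshold and 353 not, and 21 of 72 called results passed in every setting. The naming rule asked for arrays that do not overlap among the largest changes. For such genes, leaving out arrays or changing the model cannot turn the sign. The kept direction is thus largely fixed by the selection and gives no separate support. Of values not called, 3661 stayed on the same side, 133 passed and 16 reversed. List calls passed in 994 tests and not in 286. With the block, lists not called passed at 16 h minus 4 h (cytotoxic machinery 0.0447, glycolysis and hypoxia 0.0302, NK transcription factors 0.0270), at 64 h minus 16 h (NK cell receptors and adaptors 0.0126) and at 64 h minus 4 h (metallothioneins and NK transcription factors, both 0.0362). The block changed no other list call than these and those named beside their results. The cause of the changes below was not tested, apart from the smaller number of arrays where some were left out.

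Of genes called, agonist against control gave at 4 h 1 with the highest offset and 1 with only the comparison's arrays (0 otherwise). At 16 h it gave 171 probe sets, 145 of them with 1 gene, when each was tested on its own, and in genes 590 with the block, 406 with a random block, 68 without a trend and 270 with array weights, and 36 to 101 without single arrays. The shift to a common median moved the median change of all genes at 16 h from -0.04 to 0.08. At 64 h it gave 179 with the block, 105 with a random block, 6 with only its arrays, 0 without replicate 1 and 2 to 30 without single arrays. The effect at 16 h minus that at 4 h gave 5 (highest offset), 3 (60th percentile), 27 (block), 9 (random block), 6 (weights), 2 (only its arrays), 0 (without replicate 1) and 1 to 3 without single arrays; that at 64 h minus 16 h gave 1 (highest offset) and 4 (block). Control at 16 h against 4 h gave 17 with the highest offset, quantile normalization or the 60th percentile, 5 with the median shift, 139 with the block, 86 with a random block, 20 with weights, 5 with only its arrays, 3 without replicate 1 and 1 to 22 without single arrays. Control at 64 h against 4 h gave 2 (highest offset), 243 (block), 119 (random block), 8 (weights), 3 (without replicate 1) and 1 to 4 without single arrays.

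Of lists called, agonist against control gave at 4 h 1 with fry and 3 to 7 without single arrays, at 16 h 6 with an estimated correlation and 8 with fry, and at 64 h 3, 4, 6 without replicate 1 and 7 to 15 without single arrays. The effect at 16 h minus 4 h gave 0 and 0 (estimated, fry), that at 64 h minus 16 h 1 and 0, and that at 64 h minus 4 h 0 and 0, with 5 after quantile normalization, 3 with an offset of 1, 2 without a filter, 4 without replicate 1 and 2 to 10 without single arrays. Control at 16 h gave 1 and 1, 2 without replicate 1 and 2 to 6 without single arrays, and control at 64 h 0 and 0, and 4 to 10 without single arrays.

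Pearson's r across genes of the effects at 4 and 16 h was 0.0800 without a filter and 0.108 to 0.179 without 1 replicate number. At 16 and 64 h it was 0.341 with an offset of 1, 0.382 with 64, 0.186 without a filter and 0.297 to 0.312 without 1 number, and the shared calls were 76 with the block and 0 to 7 without 1 number (0 is fixed without replicate 1, where no gene was called at 64 h). At 4 and 64 h it was 0.0200 without a filter and 0.0488 to 0.0856 without 1 number.

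Reversed values were those of the KIR2DL4 level, agonist vs control at 16 h, at -0.00254 with an offset of 64, -0.0147 with the highest, -0.0125 after quantile normalization and -0.45 to 0.30 without single arrays, and of the KIR2DL4 level, agonist vs control at 4 h, at -0.0193 to 0.90. CDKN1A at 4 h was 0.38 without replicate 1 and -0.81 to 0.26 without single arrays. PRKDC at 4 h was 0.0120 with the median shift, 0.0729 with weights, 0.18 without replicate 1 and -0.10 to 0.13 without single arrays, and at 64 h -0.0030 to 0.42. IL6 at 64 h was -0.0111 without replicate 1 and -0.0787 to 1.53 without single arrays. ITGA2B at 64 h was 0.0220 without replicate 1 and -0.51 to 0.0948 without single arrays, and NR4A3 at 4 h -0.14 to 1.45.

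Genes under the 40th percentile of mean signal were tested only without the filter, which called 91 genes at 16 h, 87 of the 112 among them, and 23 at 64 h, with all 20 among them.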

Other observations

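Genes of cytosolic aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNA for translation, stood among those called higher with the agonist at 16 h: GARS1 rose by 1.34 ± 0.19 (adjusted p = 0.000681), CARS1 by 0.94 ± 0.20 (adjusted p = 0.0184), WARS1 by 2.06 ± 0.47 (adjusted p = 0.0312) and TARS1 by 1.10 ± 0.25 (adjusted p = 0.0322). The family was picked after these 4 of its 17 tested members (20 listed) had been seen among the calls, and the test used only the 13 others. Of these 13, 12 were above 0, with a median log2 fold change of 0.52. Their mean log2 value was 10.99 ± 0.16 in control and 11.48 ± 0.17 in agonist arrays (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest possible). That test ignores the pairs by replicate number, and a sign-flip test of 4 pairs allows no value under 0.125. Against all other genes camera gave p = 2.31e-07 with the preset correlation and 0.00975 with an estimated one. The median was 0.05 at 4 h and 0.17 at 64 h; whether the effect differed between times was not tested. MTHFD2, a folate enzyme of mitochondria, rose by 2.38 ± 0.38 at 16 h (adjusted p = 0.00178). A rise of the synthetase family as a group at 16 h, as in a response to amino acid demand, may be a hypothesis for separate samples, since it was found and tested on the same arrays.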
